A study of Mus musculus with 9 samples.

How the data were processed

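RNA was sequenced from colon tissue of 9 C57BL/6J mice in 3 groups of 3, per the labels. The normal group was untreated. The model group drank 2.5% (w/v) dextran sulfate sodium (DSS), which injures the colon lining, for 8 days and then plain water for 6 days, with saline by mouth. The MG group had the same DSS and received methyl gallate, a plant phenol, at 200 mg/kg by mouth once a day for 6 days. The study had 6 groups of 10 mice, and the other groups are not analysed here. Libraries were made from 1 µg of total RNA with a TruSeq kit, per the labels' protocols. Every sample title also carries the tag "rep2", whose meaning is not given in the sources used here. The aligner, the counting, the test, any batch correction and the genome build are likewise not given in the sources used here.

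The authors deposited 2 tables, model against normal and MG against model, each with the 6 libraries of its comparison. Library columns were matched to samples by the group letters and the number in the sample titles, and 0 library columns were left unmatched. Per the file headers, each gene has a level in each library and the authors' mean level per group, taken here as a signal because no source states its unit. The deposited tables also give the authors' fold change (a ratio), its log2 and a p-value with an adjusted p-value. Both tables hold only genes that the authors marked as significant, 129 in the first and 15 in the second. From adjusted p, rank and p, the number of genes the authors tested was computed as 18136 and 20278. All 129 and all 15 adjusted p-values followed from their rank within 1%, so no call with a lower p-value is missing between the listed ones.

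The deposited levels are not plain measurements. Beyond the second decimal, all libraries of a gene above 0 other than normal 3 shared the same digits in 129 of 129 genes of the first table and 15 of 15 of the second, within a tolerance of 1e-05. A library other than normal 3 was at 0, and so outside this count, in 20 and 2 genes. At the tolerance tried first, 2e-06, this held in 128 and 15 genes, and the wider one was chosen after that count was seen. In normal 3 the digits were the complement in 106 of the 106 genes where it was above 0, at both tolerances. In the first table an amount was therefore added to the other libraries and taken from normal 3, or the reverse, and values were held at 0 or above. The second table lacks the normal libraries. MG libraries and normal 3 can thus be seen together only in the 6 genes of both tables. No label or header says why. Normal 3 was at 0 in 23 genes of the first table. The authors' log2 fold change differed from the log2 ratio of the deposited group means by a median of 0.60 in the first table and 0.91 in the second. The gap was over 1 in 46 of 126 genes and 6 of 15 genes, and reached 21.5 and 3.36. It was wide in named genes too, with 8.39 by the authors' deposited table against 3.03 from the levels for Retnlg, 7.19 against 3.07 for S100a8 and -1.42 against -5.83 for Fabp2. Sizes of change therefore depend on the scale, with the same sign in 126 of 126 and 15 of 15 genes that had a ratio. Fold changes below are the authors', and levels are given per library only to show the spread. Reads cannot be recovered from these levels, so depth is unknown and no counting interval is given.

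The design fixed before the data were examined foresaw counts, normalized values, or tables of the authors' own calls. The tables hold the third kind with shifted levels beside it, so the comparisons rest on the authors' calls at adjusted p under 0.05. MG against normal was not tested, since no single table holds both groups. Limma 3.58.1 in R 4.3.3 was run with a trend on log2(level + 1) as a second look at the listed genes with a mean level above 1, with p-values adjusted over the list alone. These genes were selected by the authors on the same libraries, so this is not independent evidence. Adding 1 makes the differences of low genes smaller than the log2 ratio of their levels. Against the authors' log2 fold changes the limma differences went both ways. Retnlg was at 2.93 in limma against 8.39 by the authors, and Fabp2 at -6.44 against -1.42.

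34 gene lists were fixed before the data were examined. For lists with at least 3 called genes, the split into higher and lower was set against the other called genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 8 lists. Enrichment of each of the 34 lists among the called genes was added after the genes were seen, by a hypergeometric test that takes all list members as tested and ignores expression level. Genes named below are the 10 highest and 10 lowest log2 fold changes per comparison among called genes with a symbol and without overlap of libraries, leaving out predicted genes, symbols with -ps and receptor segments. This rule reads the symbol only, so Gsdmcl2 is named although GENCODE M21 classes it as a transcribed pseudogene. Up to 4 called members per list with the smallest adjusted p, the genes called in both comparisons, and Tlr4, Myd88, Rela, Nfkb1, Tnf, Il6 and Il1b complete the rule. Any other gene named was chosen after its values were seen. Gene types came from GENCODE M21, which held 123 of 123 and 13 of 13 Ensembl identifiers. The other 6 and 2 are assembled loci named MSTRG. No coordinates are given, because the build is not known.

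Limma was tested on 2000 simulated genes with the means and spreads of the listed genes, model against normal. It recovered 13.4%, 38.8% and 51.5% of changes of 1, 2 and 3 on the log2 scale, and called 0.333% of the unchanged genes. In the simulation 1800 of the 2000 genes were unchanged, whereas every listed gene had been called by the authors. These rates therefore need not hold for the fits on the listed genes. The list tests were also tested on simulated data. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used. Alternatives were other thresholds, fold minimums, pseudocounts and filters, a block for the replicate number, and leaving out each library.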

Results

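Gene expression was measured by RNA sequencing in the colon of 3 normal mice, 3 mice with DSS colitis given saline (model) and 3 mice with DSS colitis given methyl gallate (MG). The labels number the mice within each group and state no shared litter, cage or day. The limma p-values per gene measure only the spread between these samples. The authors' test is not given in the sources used here, so what spread their p-values measure is unknown. The list tests, Fisher's and hypergeometric, take genes as independent units, so they measure no spread between mice. Genes that change together count in them as separate genes. Depth is unknown, because the tables hold levels of an unstated unit.

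The first comparison asked which genes differ in colon after DSS with saline by mouth. The normal mice were untreated, so DSS and oral dosing cannot be told apart in it. Genes of neutrophils, the white cells that enter inflamed tissue first, were higher in model than in normal colon, and genes of smooth muscle contraction were lower. The authors called 129 of 18136 tested genes in the authors' deposited table, of which 88 were higher and 41 lower. Slpi, a protease inhibitor of mucosal surfaces, had the smallest adjusted p, with a log2 fold change of 4.95 and adjusted p = 2.47e-35 in the authors' deposited table. Its level was 7.15, 5.32 and 17.5 in the normal libraries and 261, 167 and 158 in the model libraries. Pla2g4c, a phospholipase, fell by 5.76 on the log2 scale in the authors' deposited table. The 3 model libraries did not overlap the 3 normal libraries in 112 of the 129 genes, and all 3 model libraries lay beyond normal 1 and normal 2 in 126 genes, 85 higher and 41 lower. Chance gives 10% and 20% for genes not chosen on these libraries, but these were, so the counts describe the listed genes and test nothing.

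Neutrophil markers made up the largest group. The list has 37 members, and the uncalled ones have no level here. The 13 called members were all higher, with log2 fold changes from 1.87 to 8.39 in the authors' deposited table. They included Retnlg at 8.39, Ngp at 7.36, the calprotectin subunit S100a8 at 7.19, the chemokine receptor Cxcr2 at 5.77, Trem1 at 4.48, the matrix protease Mmp9 at 3.73, lactoferrin (Ltf) at 3.30 and Wfdc17 at 2.52. Ngp was at a tied lowest level of 0.456 in 2 libraries and at 0 in normal 3, with a limma difference of 1.26. The split of the 13 called members differed from that of the other called genes by Fisher's exact test (adjusted p = 0.0366). By chance 0.263 members would be called (enrichment adjusted p = 6.7e-18, added after the genes were seen). Genes low in normal colon, such as Cxcr2 at 0.393, 0.413 and 0 in the normal libraries, can hardly be called lower, which limits the direction test. Normal 3 was at 0 in 9 of the 13 called members, and all 13 had model libraries beyond normal 1 and normal 2. In limma without normal 3 and with no filter on low levels, Retnlg, Ngp, Hp, S100a8 and Trem1 did not pass. Their adjusted p over the list alone ran from 0.0566 to 0.116, and the other called members passed. Hp, S100a8 and Trem1 did not pass with normal 3 either. The limma difference of S100a8 went from 3.71 to 2.06 and that of Retnlg from 2.93 to 1.89. S100a8 was at 28.7, 30.3 and 0 in the normal libraries and at 126.5, 319 and 49.7 in the model libraries.

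Smooth muscle genes went the other way. Of the 30 list members 7 were called, and the uncalled ones have no level here. All 7 called members were lower, with log2 fold changes from -1.87 to -1.29 in the authors' deposited table. Synpo2 was at -1.87, desmin (Des) at -1.63, the smooth muscle myosin Myh11 at -1.52 and the enteric actin Actg2 at -1.51. Fisher's exact test of direction gave adjusted p = 0.0018, and 0.213 members would be called by chance (enrichment adjusted p = 2.4e-08, added after the genes were seen). Myh11 also varied among controls, at 105, 269 and 211 in the normal libraries against 26.4, 26.7 and 42.8 in the model libraries. Among single called members of other lists, the muscle creatine kinase Ckm was at -1.74 in the authors' deposited table.

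**Figure D1:**
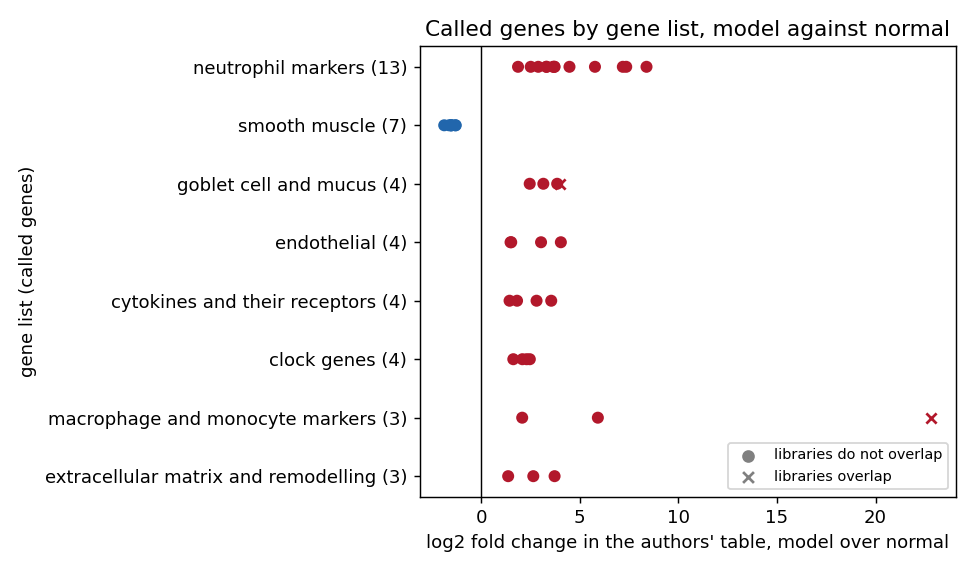
Authors' log2 fold change of model over normal (x axis) for the called genes of each fixed list with at least 3 called genes (y axis, number of genes in brackets). Each point is a gene, with a cross where libraries of the 2 groups overlap, and all 13 neutrophil markers lie above 0 and all 7 smooth muscle genes below 0.

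Another 6 lists held more called genes than chance by the test added afterwards, with all their called members higher. They have 19 to 55 members each, and uncalled members have no level here. Of 19 clock genes 4 were called, Dbp at 2.47, Nr1d1 at 2.31, Tef at 2.09 and Per3 at 1.63 in the authors' deposited table (enrichment adjusted p = 9.9e-05). Endothelial genes had 4, with Selp, which catches leukocytes on the vessel wall, at 4.04, Madcam1 at 3.04, Flt4 at 1.53 and Tie1 at 1.49 in the authors' deposited table (enrichment adjusted p = 0.00032). Goblet cell genes had 4, with Best2 at 4.02, Spink1 at 3.86, the mucus protein Zg16 at 3.16 and the trefoil peptide Tff3 at 2.46 in the authors' deposited table (enrichment adjusted p = 0.00102), and the libraries overlapped for Best2. Cytokine genes had Il33 at 3.56, Il1a at 2.81, the interleukin 1 antagonist Il1rn at 1.82 and the receptor Osmr at 1.44 in the authors' deposited table (enrichment adjusted p = 0.00138). Matrix genes had Mmp9, Mmp3 at 2.65 and decorin (Dcn) at 1.37 in the authors' deposited table (enrichment adjusted p = 0.0299). Macrophage markers had Chil3 at 5.92, Gpnmb at 2.08 and Cd209b in the authors' deposited table (enrichment adjusted p = 0.0111), but Cd209b was above its lowest tied level in model 1 only. None of these 6 lists passed the direction test fixed beforehand, where Fisher's exact test gave adjusted p from 0.408 to 0.551. Before adjustment, Fisher's p was 0.306 with 4 of 4 genes higher and 0.551 with 3 of 3. Those splits were already fully one-sided, because 88 of the 129 called genes were higher. Such short lists of higher genes could not pass, so this result says nothing about them.

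Other lists held 1 or 2 called genes. Antimicrobial genes had Slpi and lipocalin (Lcn2, 4.12), colonocyte genes had the sodium channel subunit Scnn1g (7.21) and Hsd11b2 (1.66), and chemokine genes had Cxcr2 and Cxcl5 (3.25) as log2 fold changes in the authors' deposited table. Scnn1g was at 0.490, 4.94 and 0.830 in the model libraries, so its value rests on model 2, and its limma difference of 1.05 went to 0.43 without it. Trdc (2.50), Ces2b (2.75) and Hba-a1 (2.41) were higher in the authors' deposited table, and libraries overlapped for Hba-a1. The authors' deposited table had Gsdmc2 at -2.61, Alox15 at -2.38, Krt17 at -2.20, somatostatin (Sst) at -1.71, Fabp2 at -1.42 and Ube2c at -1.30. Outside the lists, the lowest genes in the authors' deposited table included Gsdmcl2 at -3.26, Grp at -2.51, Iffo2 at -2.48, Nmu at -2.44, Stac at -2.22 and Calcb at -2.14, and Wfdc12 was at 6.83. Wfdc12 was at a tied lowest level of 0.2325 in 2 libraries, with a limma difference of 1.61.

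The series also addresses the TLR4 and NF-kB pathway. Tlr4, Myd88, Rela, Nfkb1, Tnf, Il6 and Il1b were 0 of 7 listed in either table, so no value is given for them. Of the 42 genes of the TLR and NF-kB list, 1 was called, Lbp, the binding protein for bacterial lipopolysaccharide, with a log2 fold change of 3.60 in the authors' deposited table. Its level was 2.16, 2.29 and 0 in the normal libraries and 3.91, 5.28 and 26.9 in the model libraries, and in limma it lost its call under each left-out library, with a log2 difference of 2.12 that went to 1.35 without model 3. Unlisted genes have no level here, so their change is unknown.

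The second comparison asked what methyl gallate changes in mice with DSS colitis. Inflammation-related Lcn2 and Chil3 were lower with methyl gallate than with saline, and the mast cell protease Mcpt1 was higher. The authors' deposited table called 15 of 20278 tested genes, 3 higher and 12 lower. The higher genes were Mcpt1 at 2.50, Hr at 1.56 and the fatty acid transporter Slc27a2 at 1.48 in the authors' deposited table. Among the lower genes in the authors' deposited table were the xenobiotic enzyme Cyp1b1 at -4.33, Chil3 at -3.55, Lcn2 at -2.79, the lipase inhibitor Angptl4 at -2.49, Ggt1 at -2.31, the lipocalin Apod at -1.70 and Grrp1 at -1.60. Cyp1b1 was at 3.68, 1.5 and 0.472 in the model libraries and at 0.452, 0.392 and 0.382 in the MG libraries. Mcpt1 was at 0, 1.01 and 0 in the model libraries and at 20.4, 3.42 and 34.1 in the MG libraries. Libraries did not overlap in 13 of the 15 genes, with Dio2 and Sntg1 as exceptions, and the 10% that chance gives is no test here because the genes were called on these libraries. No list had 3 called genes, so no list direction was tested, and 0 of 34 lists were enriched at adjusted p under 0.05 by the hypergeometric test added afterwards.

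Genes called in both comparisons numbered 6, and all 6 went in opposite directions. Chil3, Lcn2, Ggt1 and the assembled loci MSTRG.6196 and MSTRG.18123 were higher in model and lower with MG, and Hr, a transcriptional corepressor, was lower and then higher. Lcn2 was at 8.79, 10.6 and 0 in normal, 42.7, 76.2 and 28.9 in model and 17.3, 10.9 and 12.2 in MG libraries. Chil3 was at 2.52, 2.43 and 0 in normal, 17.5, 20.5 and 5.62 in model and 4.14, 2.42 and 3.42 in MG libraries. The log2 fold changes of both comparisons in the authors' deposited table summed to 2.37 for Chil3, 1.32 for Lcn2 and -0.04 for Ggt1. The sums were 0.346 for MSTRG.18123, 0.232 for Hr and 0.199 for MSTRG.6196. Independent lists would share 0.107 genes, or 0.0582 higher then lower and 0.00678 lower then higher. Both comparisons share the model libraries, and in 100000 simulated genes with no effect, 933 passed 0.05 in both and 100% of those went in opposite directions, so the opposite direction by itself carries no evidence. Fisher's exact test of direction among the 6 genes gave p = 0.167. That is the lowest p that 5 genes of 1 direction and 1 of the other can give, so this test could not pass. With 3 model libraries the shared group cannot be split into parts of at least 2, and part of the overlap may come from the shared libraries.

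**Figure D2:**
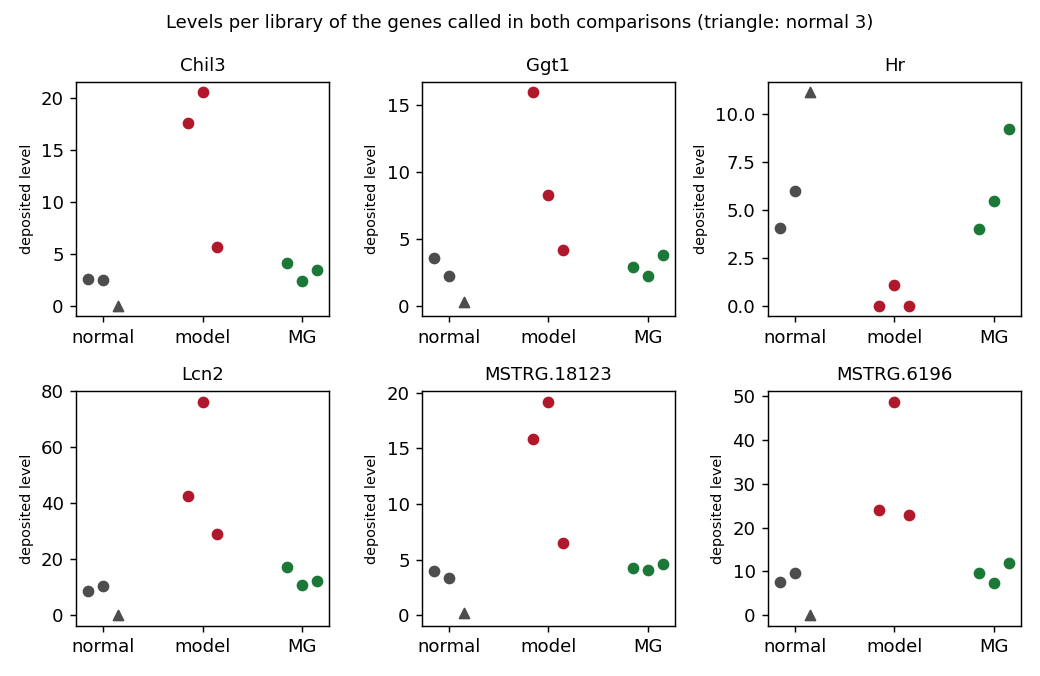
Deposited level (y axis, unit not stated) in each library of the normal, model and MG groups (x axis) for the 6 genes called in both comparisons. Each point is a library and the triangle is normal 3, which carries the opposite shift, and in Lcn2 the model libraries (42.7, 76.2 and 28.9) lie above all others.

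Limma on the listed genes, adjusted over the list alone, passed 101 of 126 genes in model against normal and 10 of 15 in MG against model, all in the authors' direction. With no filter on low levels, 63 of the 73 named gene entries passed. The other 10 did not: Angptl4, Cyp1b1 and Ggt1 in MG against model, and S100a8, Trem1, Scnn1g, Best2, Cd209b, Gsdmcl2 and Hba-a1 in model against normal. Of those 63, 39 lost their call in at least 1 fit with a library left out. Il33, Il1rn, Dcn, Spink1, Retnlg and Ngp lost it in 5 of 6 such fits and Lbp in 6 for model against normal. For MG against model, Chil3 and MSTRG.18123 lost it in 5 of 6 fits, and Lcn2, Apod and Slc27a2 in 4. Grrp1 and MSTRG.6196 lost it in 3, Mcpt1 in 2 and Hr in 0. Without normal 2 the first count was 53. Without model 1, MG 1, MG 2 or MG 3 the second was 5, 2, 3 and 5.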

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

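The authors' calls went from 129 to 51 (33 higher, 18 lower) at adjusted p under 0.01 and to 73 at an absolute log2 fold change of at least 2 for model against normal. MG against model went from 15 to 7 at adjusted p under 0.01. Of the 2 lists past the direction test, 0 passed at either limit. Neutrophil markers were tested with 9 and 12 genes, all higher, so no split of them could have been more one-sided. Smooth muscle, with 1 and 0 genes left, could not be tested. Counts restricted to genes without overlap of libraries, or to model libraries beyond normal 1 and normal 2, were chosen after seeing the data and stayed within 1.5 times. In limma the count for model against normal went from 101 to 24 at adjusted p under 0.01, to 39 at a log2 difference of at least 2 and to between 53 and 93 with a library left out. For MG against model it went from 10 to 2 at adjusted p under 0.01, to 2 at a log2 difference of at least 2 and to between 2 and 13 with a library left out. Genes passing limma in both comparisons went from 5 to between 1 and 5, with 1 without model 1, model 2, MG 1 or MG 2 and 2 without MG 3. Fewer samples lower the power of these fits, and other causes were not tested.

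With the replicate number as a block, limma passed 106 genes in model against normal, 2 in MG against model and 1 in both. Deviations of same-numbered libraries correlated across genes at 0.07, 0.12 and 0.12 in the first table and -0.29, -0.44 and 0.08 in the second. Libraries with different numbers ran from -0.44 to 0.46 in the second. These values come from selected genes and 3 libraries per group, so they neither show nor exclude a pairing. Of the 73 named gene entries, 0 reversed direction. With a library left out, 303 of 438 entries kept their side of the threshold, 129 lost it and 6 gained it, and under the other settings 186 of 219 kept it, 27 lost it and 6 gained it. Count-based tests and normalizations, a fit of all 9 samples, MG against normal and set tests over all genes were not run, since the tables hold neither counts nor all genes. Unknown depth leaves the precision of low levels unknown.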

Other observations

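All tests of explanations here were chosen or written down after the results were seen. Some immunoglobulin genes were also called in model against normal. Of them, 10 were called in the authors' deposited table, all higher, with log2 fold changes from 1.35 to 3.52, where 1.91 would be called by chance (hypergeometric p = 2.21e-05), but only 3 had libraries without overlap and 7 of the 10 did not pass limma adjusted over the list alone. All 10 had model libraries beyond normal 1 and normal 2, and normal 3 was the highest normal library in each. The overlap therefore came from normal 3, and why it was high was not tested. In limma without normal 3 and with no filter on low levels, all but 1 of the 10 passed. Their adjusted p over the list alone ran from 0.00189 to 0.0472, and the remaining gene was at 0.111. No direction test was run for these immunoglobulin genes. Their segments share sequence, so reads may be split among them, and with libraries required not to overlap the count for the whole table was 112 of 129. Fcna, Serpina3n and Igfbp5 were at 1.76, 2.40 and 2.74 in the authors' deposited table. The 3 log2 fold changes above 20 there, for mt-Nd4l (24.13), Cd209b (22.82) and Pgam1-ps2 (20.44), rest mainly on 1 model library each, and they are the 3 genes whose model libraries are not all beyond normal 1 and normal 2. No called gene came from 11 of the 34 lists in model against normal: B cells, MHC class II, interferon response, tight junctions, oxidative stress, crypt stem cells, enteric neurons and glia, adipocytes, pancreas, immediate early genes and sex-linked genes.

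The 6 genes called in both comparisons could reflect methyl gallate or chance in the model libraries that both comparisons share. If every model call were chance with the 3 groups alike, 4.42 shared calls would be expected, against the 6 seen. This lays equal parts of each deviation on the normal and model libraries. Chance in the model libraries alone would give more, so the calculation does not exclude the shared libraries. Genes with the smallest p weigh most in it, and Slpi, the first of them, was not called in MG against model. A second calculation was added after the 4.42 was known. If the authors' p-values hold, it expects 0.665 chance calls among all genes tested in MG against model. It rests on p-values from a test not given in the sources used here and on mice that may differ in severity, so chance and methyl gallate cannot be told apart. In limma without normal 3, 5 of the 6 kept their call, adjusted over the list alone, which argues against normal 3 as the whole cause for those 5, and 1 (Ggt1) did not and stays open; the 6 kept 61.1% to 86.6% of their difference.

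Lower smooth muscle genes could come from less muscle wall in the model pieces or from a change within the muscle. The SD over the 7 called members was 0.197 for the authors' log2 fold change, but 0.779 for the log2 ratio of deposited levels, which ran from -3.65 to -1.27, and 0.692 for the limma difference. Whether they fell by similar amounts thus depends on the scale, and genes chosen for passing the same test cannot decide it. The uncalled members of the list of 30 have no level here, so a fall across the whole list is unknown. Without normal 3 the 7 kept 90.5% to 96.3% of their limma difference and 6 kept their call, which argues against normal 3 as the whole cause for those 6, while 1 (Hspb7) lost its call, among 19 listed genes that did. How the tissue pieces were cut is not given in the sources used here, and the colitis itself stays open.

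Higher clock genes could come from the time of collection. Of Arntl, Clock, Npas2, Nfil3 and Cry1, which peak in the opposite phase, 0 were listed, and a gene missing from a table of calls excludes nothing. Other uncalled members of the list of 19, Per1 and Per2 among them, have no level here either. Normal 3 as the whole cause is argued against, since 4 of the 4 genes kept their call without it, with 94.4% to 118% of their limma difference. With each of the 6 libraries left out in turn, Dbp and Per3 lost their call in 4 fits, and Nr1d1 and Tef in 0. Collection times are not given in the sources used here, so time and colitis cannot be told apart.

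Of the 10 splits of the 6 libraries into groups of 3, 1 split (the real one) gave as many limma genes in each comparison. The real counts were 101 and 10, and the highest of the other splits were 0 and 1. With 10 splits the share is never under 0.1, and the genes were listed because they differ in the real split, so the counts favour it.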
